A study of Mus musculus with 12 samples.

How the data were processed

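The series measured total RNA of mouse prostate on single-colour Affymetrix expression arrays, which read each transcript with a set of short probes. Per the labels, the 12 arrays came from ventral or lateral prostate of wild-type mice or mice with a knockout of Med1, at 16 weeks of age, with 3 arrays in each of 4 groups. RNA was extracted with a column kit, and cDNA was fragmented and labelled with biotin, per the labels' protocols. The deposited values are log2 signals that the authors made with Affymetrix Expression Console and RMA (background correction, quantile normalization and summary of the probes of a set), per the submitters' processing notes, and the versions of these tools are not given in the sources used here. The labels do not say whether the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

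RMA gives every array normalized together nearly the same distribution. Sorted values had a median range of 0.0493 log2 units over the 6 ventral arrays, 0.0786 over the 6 lateral arrays and 0.388 over all 12, so the lobes look as if they were normalized in separate runs. Genotype was compared within each lobe, where this does not enter, and the comparison of the lobes is given with the caution that lobe and normalization run coincide.

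The arrays hold 45101 probe sets. The platform annotation gave 1 gene symbol to 34958, several to 932 and listed none for 9211. Symbols were updated through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, which matched 34754 of the probe sets with 1 symbol. No gene was named from a probe set with several. For each of 18194 genes the probe set with the highest mean over all arrays was kept, and 9012 genes had more than 1. The build behind the probe annotation is not given in the sources used here, so no coordinates are printed and the gene table served only for names and for which genes neighbour each other.

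Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) on a model with 4 group means over all 12 arrays, which left 8 residual degrees of freedom, with 5.68 prior degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are moderated standard errors. RMA values carry no detection calls, so signal was called low where a group mean lay under the lower quartile of all probe sets, averaged over the arrays of the lobe (4.73 log2 units in ventral and 4.52 in lateral arrays), and a difference against low signal is a lower bound. This mark was chosen after the values were seen. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, again with the correlation estimated from the residuals, and with fry. Camera sets a list against the other genes, while fry tests it against no change. The 26 lists (markers of prostate cell types and neighbouring tissues, secretory products, and pathways) held 623 genes, of which 570 were measured and the rest were not analysed here. The groups, these tests, lists and alternatives were fixed before the data were examined. So was the rule for naming genes: Med1, per lobe the 12 largest rises and 12 largest falls among genes past the threshold whose arrays do not overlap between genotypes, 6 per direction for each other contrast, and up to 4 members of smallest p per list. Uncharacterized loci were passed over. Names outside that rule are said to be chosen after their values were seen.

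The steps were tested on simulated data for the ventral genotype comparison, drawn from the means and residual standard deviations of all 18194 genes. Of 67 genes changed by 0.5 log2 units, 50 were called with the right sign, as were 65 of 67 changed by 1 and 66 of 66 changed by 2, beside 5 calls among unchanged genes. A list of 20 genes shifted by 0.4 passed camera, and 0 of 25 unshifted lists did. Noise was drawn independently for each gene, so this does not test camera on lists whose genes are correlated. In the real arrays the estimated correlation reached 0.58 in the smooth muscle list.

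The alternatives were the arrays of the comparison alone, replicate numbers as a block, quantile normalization or median centring over all arrays, removal of dim genes, other handling of probe sets, other variance models, other thresholds and each array left out. Arrays give no read depth, and the number of arrays limits the precision. Within a group, arrays correlated at 0.992 to 0.996 over probe sets (Pearson), and arrays of different lobes at 0.943 to 0.960.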

Results

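Gene expression was profiled in the ventral and lateral lobes of the prostate of wild-type mice and mice labelled as Med1 knockouts at 16 weeks of age. Med1 encodes a subunit of Mediator, the complex that links transcription factors such as nuclear receptors to RNA polymerase II. There were 3 arrays for each lobe and genotype, and array medians lay between 6.39 and 6.43 log2 units in the ventral and between 6.05 and 6.06 in the lateral samples.

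The targeted gene was examined first. In the ventral lobe, Med1 averaged 9.43 ± 0.12 log2 units in wild type and 8.86 ± 0.16 in knockout (SD, n = 3 each), a difference of -0.57 ± 0.12 (SE; limma adjusted p = 0.0119). Each ventral knockout array lay below each ventral wild-type array, and 4 of 7 Med1 probe sets passed as lower. Without KO_VP replicate 3 the difference was -0.48 and no longer passed (limma adjusted p = 0.0518). In the lateral lobe Med1 averaged 8.52 ± 0.26 in wild type and 8.39 ± 0.049 in the arrays labelled knockout, a difference of -0.13 ± 0.12 (limma adjusted p = 0.622), and 0 of 7 probe sets passed by limma, with 4 higher and 3 lower. The mean of its probe sets was higher by 0.045 (limma adjusted p = 0.794), so the direction is not settled. The difference between the lobes in this change, -0.44 ± 0.18, did not pass either (limma adjusted p = 0.136). The deleted part of Med1 is not given in the sources used here, so it is unknown whether the probe sets lie in it, and one outside it would not check the genotype. The lateral arrays are called labelled knockout throughout.

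**Figure D1:**
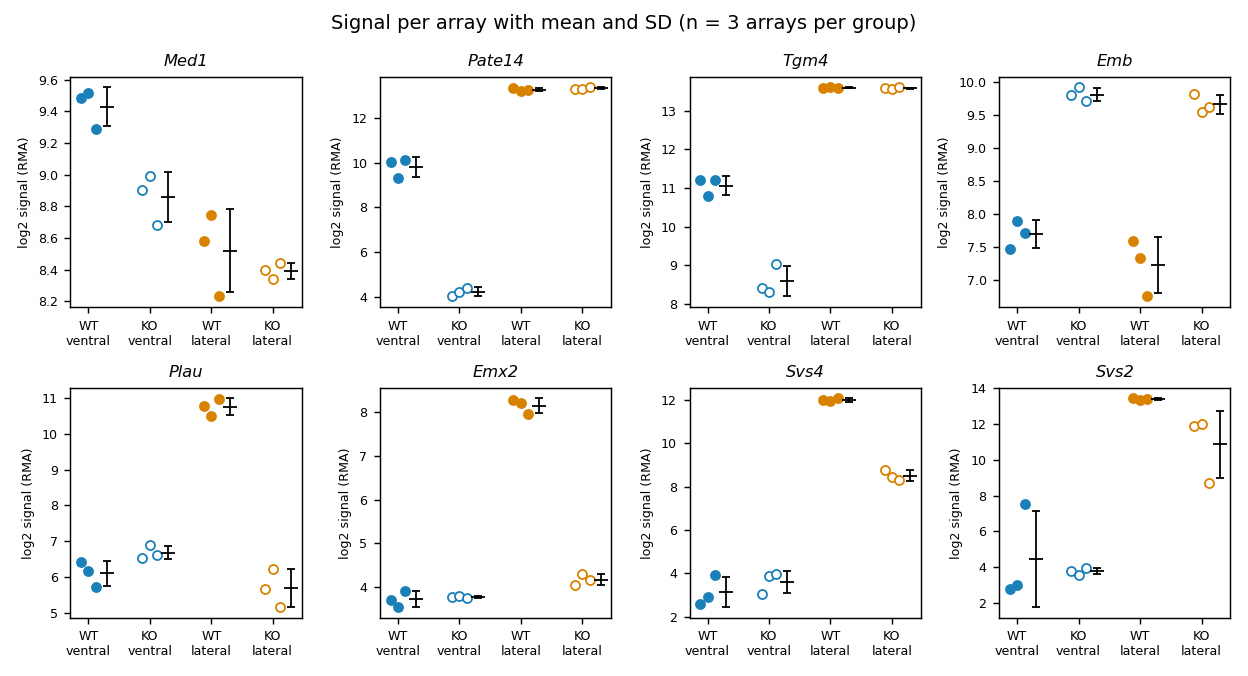
Log2 RMA signal of 8 genes on each of the 12 arrays (points, filled for wild type and open for arrays labelled knockout, blue for ventral and orange for lateral), with the mean and SD of each group of 3 beside them in black. Pate14 and Tgm4 were lower in ventral knockout arrays, Plau, Emx2 and Svs4 in lateral arrays labelled knockout, and Emb was higher in both lobes.

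Ventral knockout prostate had lost much of its signal for several secreted products. Pate14, a small cysteine-rich secreted protein, went from 9.81 to 4.23 log2 units (-5.58 ± 0.17, SE; limma adjusted p = 3.78e-10; lower in 3 of 3 arrays). Secreted products among the falls were the salivary-type mucin-like Smgc (-3.90 ± 0.35), the ribonuclease Rnase1 (-2.68 ± 0.15), the mucus-associated Fcgbp (-2.67 ± 0.19) and the lipase-related Pnliprp1 (-2.60 ± 0.17). The prostate transglutaminase Tgm4 (-2.48 ± 0.16) and the metalloprotease Mmp7 (-2.12 ± 0.12) fell as well, and limma's adjusted p for these 6 genes was at most 2.02e-05. Membrane proteins fell too, among them the cholecystokinin receptor Cckar (-2.74), the proton pump subunit Atp12a (-2.51), the retinol-binding protein receptor Stra6 (-2.49) and the amino acid transporter Slc7a12 (-2.22). Chn2 was at -2.27. Among the ventral wild-type arrays, each of these falling genes read highest in WT_VP replicate 3, where seminal vesicle genes also stood apart. The naming rule required that wild-type and knockout arrays did not overlap, so the falls did not rest on that array alone. Knockout signal was low for Pate14 (4.23), Smgc (4.51), Cckar (3.23), Pnliprp1 (4.02), Slc7a12 (3.39) and Chn2 (4.62), so these genes fell by at least the sizes given. Rises were seen in Gsdmc2 (at least 2.73 ± 0.32, from low signal of 4.71), a gasdermin, Emb (2.12 ± 0.17), a cell-surface glycoprotein, Plscr2 (2.07) and Tmem45b (2.05). Further rises were in the histone gene H2bc18 (1.71), Adam7 (1.68), the epithelial sodium channel subunit Scnn1a (1.67) and the glutathione transferase Mgst1 (1.64).

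Of 18194 genes, 1652 passed in the ventral lobe, 1069 higher and 583 lower, and 634 of these changed at least 1.5-fold. Genes whose genotypes did not overlap made up 29.5% of all genes, against 10% by chance. The count of changed genes was 1033 without WT_VP replicate 1, 941 without WT_VP replicate 3 and 1086 without KO_VP replicate 3. It was 965 with the 6 ventral arrays alone and 992 with replicate numbers as a fixed block, and lower still without both WT_VP replicate 3 and KO_LP replicate 3. Centring arrays on their medians gave 861 higher and 926 lower genes.

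Among the fixed lists, secretory and secretory-pathway genes were lower in the ventral knockout. Of 21 measured prostate secretory genes, 10 fell and 0 rose (2 higher and 10 lower adjusted over the list alone), including probasin (Pbsn, -1.28). The list had a median of -0.12 and a mean of -0.54 (camera adjusted p = 1.22e-05, adjusted p = 0.203 with an estimated correlation). The unfolded protein response and secretion list had 8 of 30 genes lower and 0 higher (0 higher and 18 lower adjusted over the list alone), among them Creb3l4, a transcription factor of secretory cells, at -0.79 and Sdf2l1 at -0.54. The list median was -0.24 (camera adjusted p = 2.13e-09, adjusted p = 0.203 with an estimated correlation). Of 26 interferon response genes, 12 fell and 1 rose (1 higher and 16 lower adjusted over the list alone), with Irf7 at -0.70, Oasl1 at -0.62 and Stat2 at -0.60. Its genes had a median of -0.47 (camera adjusted p = 5.09e-07, adjusted p = 0.0658 with an estimated correlation).

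Stromal genes moved the other way. In the smooth muscle list 9 of 15 genes rose and 0 fell (11 higher and 0 lower adjusted over the list alone), with Synpo2 at 1.17 and Actg2 at 1.03. The median over the list was 0.42 (camera adjusted p = 1.70e-09, adjusted p = 0.213 with an estimated correlation). In the fibroblast and matrix list 13 of 21 rose and 1 fell (17 higher and 1 lower adjusted over the list alone), with periostin (Postn) at 0.88, Col1a2 at 0.58 and the exception Col6a3 at -1.19. The list median was 0.44 (camera adjusted p = 1.70e-09, adjusted p = 0.203 with an estimated correlation). Whether the ventral knockout samples held a larger share of stroma was not tested. The list for oxidative phosphorylation was higher, with 2 of 43 genes higher and 0 lower (0 higher and 0 lower adjusted over the list alone). Its median was 0.15 (camera adjusted p = 3.40e-04, adjusted p = 0.450 with an estimated correlation). So was that for apoptosis and castration-type regression, with 6 of 16 higher and 0 lower (7 higher and 1 lower adjusted over the list alone). Its median was 0.13 (camera adjusted p = 0.00508, adjusted p = 0.213 with an estimated correlation). Of the 26 lists, 7 passed camera and 0 with an estimated correlation, while 11 passed fry. The luminal epithelium list had a median of -0.033 (camera adjusted p = 0.813) and the androgen-response list 0.021 (camera adjusted p = 0.985). In the latter 6 of 49 genes rose and 4 fell (7 higher and 4 lower adjusted over the list alone) and the mean of -0.018 had the other sign.

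**Figure D2:**
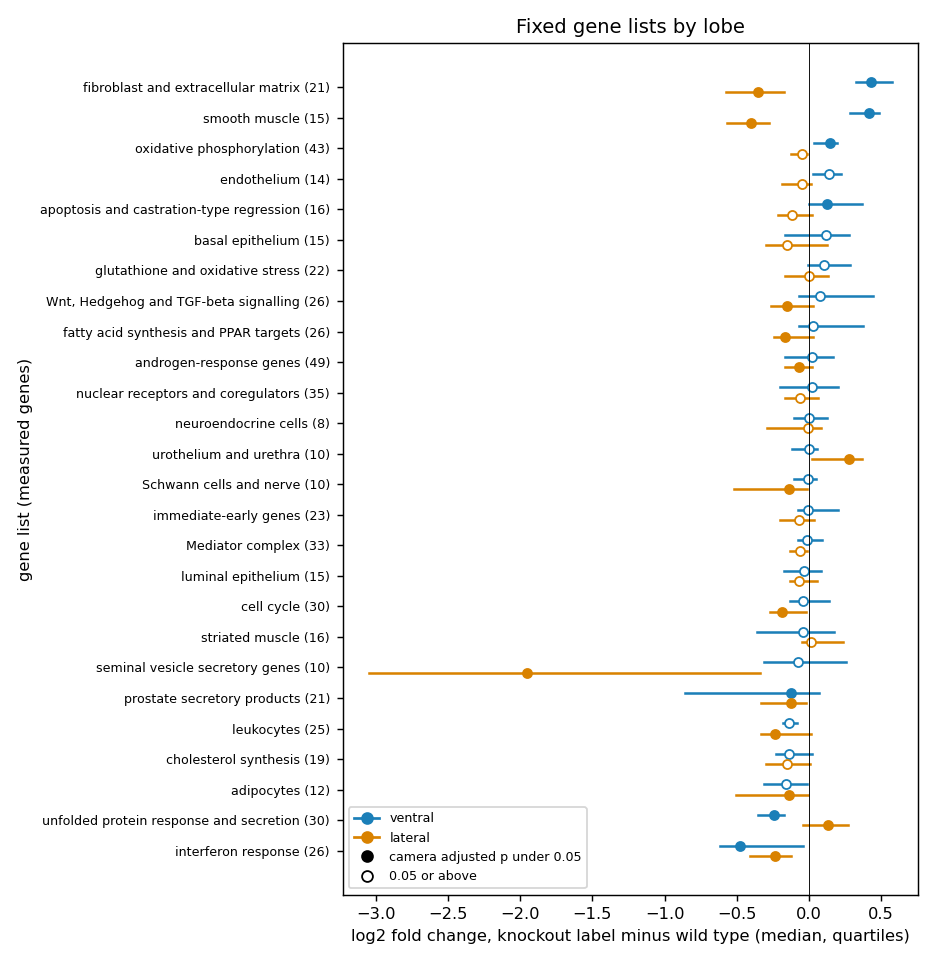
Median log2 fold change between arrays labelled knockout and wild-type arrays (horizontal axis) of each of the 26 fixed gene lists, with the quartiles over its genes as bars, in the ventral (blue) and lateral (orange) lobe. Filled points passed camera at its preset correlation, and the smooth muscle list lay at 0.42 in the ventral and -0.40 in the lateral lobe.

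In the lateral prostate, the arrays labelled knockout had lost most of the signal of several genes. Cyp4a12a, a fatty acid hydroxylase, fell by 5.70 ± 0.36 log2 units (SE, limma adjusted p = 5.54e-07; lower in 3 of 3 arrays), and the plasminogen activator Plau went from 10.74 to 5.69 (-5.05 ± 0.23, limma adjusted p = 1.21e-08). Transcription factors were among the falls, with the homeobox gene Emx2 at -3.99 ± 0.11, the Ets factor Elf5 at -3.92 ± 0.13 and the forkhead factor Foxi1 at -2.96 ± 0.16. Further falls were in the beta-defensin Defb42 (-4.43), the neurofilament gene Nefh (-4.20), the cysteine dioxygenase Cdo1 (-3.47), the glycolytic regulator Pfkfb3 (-3.06) and Gsdmc2 (-2.83). Signal in the arrays labelled knockout was low for Cyp4a12a (3.74), Emx2 (4.17), Nefh (4.21), Foxi1 (3.45) and Gsdmc2 (3.54), so their falls are lower bounds too. Rises were seen in Emb (2.44 ± 0.17), the protease-inhibitor-like Wfdc6a (2.20), the glycosyltransferase B4galnt2 (1.93) and Atp13a4 (1.89). Others were in H2bc18 (1.86), transthyretin (Ttr, at least 1.85 from low signal of 4.40), Tmem267 (1.60), the aminopeptidase Anpep (1.51) and the protease inhibitor Slpi (1.45).

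In the lateral lobe 916 genes passed, 294 higher and 622 lower, and 423 changed at least 1.5-fold. Genes without overlap between the genotypes made up 26.9%, against 10% by chance. The count of changed genes was 588 without WT_LP replicate 2, 499 without WT_LP replicate 3 and 513 without KO_LP replicate 2, and 568 after the dimmest 60% of genes were left out. Centring arrays on their medians gave 409 higher and 513 lower genes.

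Seminal vesicle secretory genes formed the list with the largest shift. Of 10 measured, 5 fell and 0 rose (0 higher and 7 lower adjusted over the list alone), with Svs4 at -3.49, Svs5 at -3.36, Svs6 at -2.43 and Svs3a at -1.47. Its genes had a median of -1.95 (camera adjusted p = 1.98e-08, adjusted p = 0.0400 with an estimated correlation). This was the only lateral list past the threshold with an estimated correlation. In KO_LP replicate 3, Svs2 read 8.71 and Pate4 8.26, against 11.89 and 11.11 in KO_LP replicate 1 and 11.99 and 11.35 in KO_LP replicate 2. Smooth muscle genes fell in 6 of 15 cases and rose in 0 (0 higher and 12 lower adjusted over the list alone), with Synm at -0.73 and Pgm5 at -0.66. The median over the list was -0.40 (camera adjusted p = 3.35e-09, adjusted p = 0.179 with an estimated correlation). In the fibroblast and matrix list 9 of 21 fell and 0 rose (0 higher and 13 lower adjusted over the list alone), with lumican (Lum) at -1.21 and Pdgfra at -0.75. The list median was -0.35 (camera adjusted p = 3.35e-09, adjusted p = 0.138 with an estimated correlation). Interferon response genes fell in 5 of 26 cases and rose in 0 (1 higher and 9 lower adjusted over the list alone), with Rtp4 at -0.97 and Oasl2 at -0.82. Its genes had a median of -0.23 (camera adjusted p = 4.24e-05, adjusted p = 0.0870 with an estimated correlation). The urothelium list was higher (2 of 10 genes higher and 0 lower, 4 higher and 0 lower adjusted over the list alone, median 0.28; camera adjusted p = 0.00307, adjusted p = 0.138 with an estimated correlation), with Upk1a at 0.68 and Upk3b at 0.73. Also higher was the unfolded protein response and secretion list (3 of 30 higher and 0 lower, 7 higher and 0 lower adjusted over the list alone, median 0.13; camera adjusted p = 0.00377, adjusted p = 0.369 with an estimated correlation), with Syvn1 at 0.55.

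Further lists passed as lower at the preset correlation, in the order leukocytes, cell cycle, adipocytes, prostate secretory products, Schwann cells and nerve, fatty acid synthesis and PPAR targets, Wnt, Hedgehog and TGF-beta signalling, and androgen-response genes. Of the leukocyte genes 4 of 25 fell and 0 rose, 0 higher and 7 lower adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.00352, adjusted p = 0.260 with an estimated correlation). Among cell cycle genes 2 of 30 fell and 0 rose, 0 higher and 2 lower adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.00375, adjusted p = 0.177 with an estimated correlation). For adipocytes 2 of 12 fell and 0 rose, 0 higher and 4 lower adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.00501, adjusted p = 0.138 with an estimated correlation). Of secretory products 5 of 21 fell and 0 rose, 1 higher and 7 lower adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.00676, adjusted p = 0.236 with an estimated correlation). Among nerve genes 4 of 10 fell and 0 rose, 0 higher and 4 lower adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.0144, adjusted p = 0.138 with an estimated correlation). For fatty acid synthesis 3 of 26 fell and 1 rose, 2 higher and 3 lower adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0212, adjusted p = 0.260 with an estimated correlation). Of the signalling genes 3 of 26 fell and 1 rose, 1 higher and 5 lower adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0264, adjusted p = 0.260 with an estimated correlation). Among androgen-response genes 2 of 49 fell and 0 rose, 0 higher and 2 lower adjusted over the list alone, with a median of -0.066 (camera adjusted p = 0.0497, adjusted p = 0.439 with an estimated correlation). Ccnd1 of the cell cycle list was at -1.46 and the iron carrier Lcn2 of the secretory list at -1.74. The last 3 of these calls rested on single arrays and on the processing. Without WT_LP replicate 1 the camera adjusted p was, in the same order, 0.05003, 0.0623 and 0.0708. Without KO_LP replicate 2 it was 0.0620, 0.0620 and 0.310. The androgen-response call was also lost without WT_VP replicate 1 (0.0519), WT_VP replicate 2 (0.0546), KO_VP replicate 1 (0.0579), WT_LP replicate 3 (0.0989) and KO_LP replicate 3 (0.0523). Quantile normalization over all arrays ended the same 3 calls (camera adjusted p = 0.0714, 0.0714 and 0.448), as did leaving out the dimmest 40% of genes (0.310, 0.0959 and 0.314), which also ended those of nerve genes (0.871) and secretory products (0.160). Median centring (0.0618) and a fixed replicate block (0.0591) each ended the androgen-response call. By fry, which asks another question, that list did not pass either (fry adjusted p = 0.0810). In all, 14 of 26 lists passed camera and 16 passed fry, and the luminal epithelium list had a median of -0.068 (camera adjusted p = 0.526).

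Some genes were higher in both lobes. Averaged over the lobes, Emb rose by 2.28 ± 0.12 (SE; limma adjusted p = 1.29e-07), H2bc18 by 1.78 ± 0.22, B4galnt2 by 1.55 ± 0.12, Tmem267 by 1.42 ± 0.19, Ttr by 1.29 ± 0.17 and Bex1 by 1.27 ± 0.087 (limma adjusted p at most 4.51e-04). For these 6 genes the difference between the lobes did not pass, with adjusted p from 0.0537 to 0.867, which does not show that the rises were equal. Ttr rose by at least 1.85 in the lateral lobe, from low signal (4.40), and by 0.73 in the ventral lobe without passing (limma adjusted p = 0.0731). B4galnt2 rose by 1.93 in the lateral and 1.18 in the ventral lobe.

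Over the mean of both lobes, which a change in 1 lobe can carry, 1024 genes passed, 491 higher and 533 lower. At least 2-fold, 15 were higher and 44 lower, and the largest falls of this contrast are not listed here. With each array left out the count ranged from 778 to 1115, and it was lower still without both WT_VP replicate 3 and KO_LP replicate 3. The interferon list fell in 14 of 26 genes and rose in 0 (1 higher and 16 lower adjusted over the list alone; camera adjusted p = 1.45e-10, adjusted p = 0.0141 with an estimated correlation). Its median was -0.47 in the ventral and -0.23 in the lateral lobe, and camera did not separate the lobes (adjusted p = 0.295). The adipocyte list had 3 of 12 genes lower and 0 higher (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 4.10e-04, adjusted p = 0.0439 with an estimated correlation), with no call for a difference between the lobes (camera adjusted p = 0.680). Prostate secretory products passed as lower with 10 of 21 genes lower and 0 higher (1 higher and 11 lower adjusted over the list alone; camera adjusted p = 8.49e-10, adjusted p = 0.0270 with an estimated correlation), but camera at the preset correlation set the lobes apart (camera adjusted p = 0.0157, adjusted p = 0.276 with an estimated correlation). Seminal vesicle secretory genes also passed, with 5 of 10 lower and 0 higher (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 8.75e-07, adjusted p = 0.0270 with an estimated correlation), on the lateral fall alone. Their ventral median was -0.074 (camera adjusted p = 0.987), and the lobes differed by a median of 1.77 (camera adjusted p = 2.20e-04, adjusted p = 0.159 with an estimated correlation). In ventral wild-type arrays 7 of the 10 had low signal. Leukocyte markers passed as lower too, with 4 of 25 lower and 0 higher (1 higher and 6 lower adjusted over the list alone, median -0.11; camera adjusted p = 0.00424, adjusted p = 0.368 with an estimated correlation). In all, 9 lists passed camera at the preset correlation, the others being cell cycle, cholesterol synthesis and unfolded protein response and secretion (lower) and urothelium (higher), none of them with an estimated correlation (adjusted p at least 0.327).

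Of the genes that passed in both lobes, 111 changed in the same direction and 150 in opposite directions. There were 72 genes higher in both, against 17.3 if the lobes were independent, and 39 lower in both, against 19.9. Genes higher in the ventral and lower in the lateral lobe numbered 141, against 36.5, and the reverse 9, against 9.42. These expected numbers are no baseline for unrelated effects, since both lobes share a variance per gene in 1 fit and overlap in opposite directions was in excess too, so no p is given. Across genes, which are not independent replicates, the log2 fold changes of the lobes had a Pearson r of -0.059 and a Spearman rho of -0.125.

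**Figure D3:**
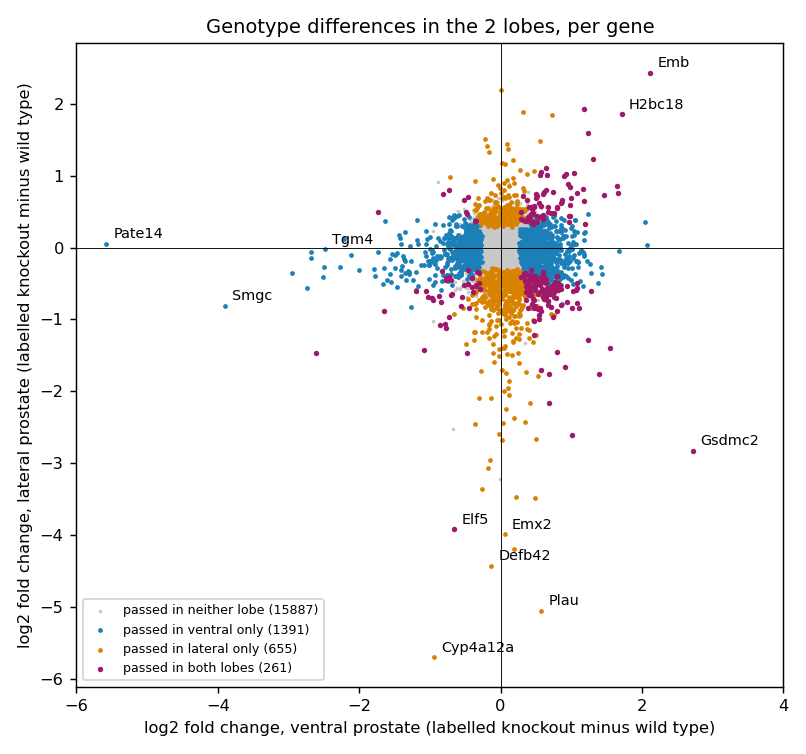
Log2 fold change of each of 18194 genes between arrays labelled knockout and wild-type arrays in the ventral lobe (horizontal axis) and the lateral lobe (vertical axis), coloured by the lobes in which the gene passed. Most genes that passed lie along 1 axis, and Emb and H2bc18 lie at the upper right.

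Whether the genotype effect differed between the lobes was tested directly. For 1693 genes the ventral effect differed from the lateral one, 1184 with the ventral effect higher and 509 with it lower. Plau (5.63 ± 0.33, ventral minus lateral effect, SE; limma adjusted p = 3.30e-07), Gsdmc2 (5.55 ± 0.45), Cyp4a12a (4.76 ± 0.51), Nefh (4.39 ± 0.20), Defb42 (4.30 ± 0.19) and Emx2 (4.05 ± 0.16) lay at the upper end. At the lower end lay Pate14 (-5.63 ± 0.24), Smgc (-3.09 ± 0.49), Fcgbp (-2.62 ± 0.27), Rnase1 (-2.54 ± 0.21), Tgm4 (-2.46 ± 0.23) and Slc7a12 (-2.34 ± 0.42). Pate14, Smgc and Slc7a12 fell to low signal in the ventral knockout, so their differences are lower bounds. Gsdmc2 rose in the ventral lobe from low signal and fell to low signal in the lateral lobe. Ventral wild-type signal was low for Cyp4a12a (3.80), Nefh (4.27), Defb42 (4.23) and Emx2 (3.71), which left little room for a fall, so these differences do not tell a lobe-dependent effect from a gene with little ventral signal. In all this held for 84 of the 1693 genes, those that fell in 1 lobe without passing in the other, where wild-type signal was low. The smooth muscle and the fibroblast and matrix lists had higher ventral effects in 13 of 15 genes (14 higher and 0 lower adjusted over the list alone) and 16 of 21 genes (18 higher and 1 lower adjusted over the list alone). For these stromal lists, a differing share of stroma in the samples was not told apart from a genotype effect. Of the lists, 12 of 26 passed camera at the preset correlation but 0 with an estimated one (smooth muscle adjusted p = 1.82e-13, then 0.159). The count of genes was 1103 without WT_LP replicate 3 and 1093 without the dimmest 60% of genes, and median centring gave 901 higher and 987 lower. It was lower still without both WT_VP replicate 3 and KO_LP replicate 3.

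Genes of secreted products were among those that set the lobes of wild-type mice apart. The seminal vesicle-type products Pate4 (9.50 ± 0.90, lateral minus ventral, SE; limma adjusted p = 5.14e-07), Svs2 (8.94 ± 1.02) and Svs4 (8.85 ± 0.29) were at least that much higher in the lateral lobe, with Glb1l3 (7.25 ± 0.19), Nlrp10 (6.86 ± 0.24) and Defb42 (6.77 ± 0.14). Higher in the ventral lobe were the protease inhibitor Spink5 (-7.95 ± 0.45), Mug1 (-7.01 ± 0.30), Lrrc52 (-6.97 ± 0.19), Tex24 (-6.97 ± 0.17), the secretoglobin Scgb2b27 (-6.85 ± 0.28) and the cystatin Csta1 (-6.75 ± 0.75). On the lower side signal was low for all of these but Csta1, with Pate4 (3.97), Svs2 (4.45), Svs4 (3.13), Glb1l3 (4.18), Nlrp10 (4.26) and Defb42 (4.23) in ventral arrays and, besides Lrrc52, Spink5 (4.35), Mug1 (3.95), Tex24 (2.32) and Scgb2b27 (3.45) in lateral arrays. These differences are lower bounds and their order is not read. In WT_VP replicate 3, Svs2 read 7.55, against 2.80 and 2.99 in the other ventral wild-type arrays, and Pate4 read 6.58, against 2.68 and 2.66. In total 12384 genes passed, 2240 higher and 10144 lower in the lateral lobe, with a median difference over all genes of -0.34. Because the lobes look separately normalized, this imbalance rests on the scaling. Quantile normalization over all arrays shifted the median by 0.39 and gave 5773 higher and 4667 lower, and median centring gave 5396 and 5416. Lobe and normalization run cannot be told apart. Seminal vesicle tissue in the wild-type lateral samples, left open below, would also raise Pate4, Svs2, Svs4 and the seminal vesicle list here. Of the 26 lists 15 passed camera, which sets a list against the other genes, and 3 passed with an estimated correlation. They were seminal vesicle secretory genes (median 4.80, camera adjusted p = 4.49e-12, adjusted p = 0.0115 with an estimated correlation), basal epithelium (0.54, camera adjusted p = 4.96e-07, adjusted p = 0.0191 with an estimated correlation) and Wnt, Hedgehog and TGF-beta signalling (0.41, camera adjusted p = 1.70e-07, adjusted p = 0.0438 with an estimated correlation).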

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

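All tests of explanations below were chosen only after the result they address was seen, the rule for lateral tissue was set again after its own values were seen, and the other groupings of the arrays were computed after the gene counts.

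A genotype effect that differed between the lobes by limma's test of the difference (adjusted p under 0.05) marked 69 of 97 named genes. Many were named for a large change in 1 lobe or in this contrast, so the share says nothing about other genes. With the ventral effect higher, the log2 differences (ventral minus lateral effect) were Plau 5.63, Gsdmc2 5.55, Cyp4a12a 4.76, Nefh 4.39, Defb42 4.30, Emx2 4.05, Svs4 3.98, Cdo1 3.69, Elf5 3.26, Svs5 3.11, Pfkfb3 2.89, Foxi1 2.81, Svs6 2.78, Defb9 2.33, Hoxd8 2.28, Lcn2 2.10, Hoxd9 2.04, Plscr2 2.03, Defb11 1.96, Adam7 1.73, Ccnd1 1.71, Lum 1.71, Synpo2 1.70, Tmem45b 1.70, Actg2 1.63, Dbp 1.52, Pdgfra 1.41, Svs3a 1.36, Pgm5 1.10, Synm 1.09, Postn 1.09, Col1a2 1.04, Defb13 1.00, Hoxb4 0.99, Scnn1a 0.91, Hoxb2 0.82, Mgst1 0.78, Nr1d1 0.78, Hoxb3 0.77 and Bhlhe40 0.59. With the ventral effect lower, they were Pate14 -5.63, Smgc -3.09, Fcgbp -2.62, Rnase1 -2.54, Tgm4 -2.46, Slc7a12 -2.34, Stra6 -2.23, Wfdc6a -2.19, Cckar -2.18, Atp12a -2.10, Mmp7 -2.02, Chn2 -2.01, Anpep -1.73, Atp13a4 -1.57, Gsdma -1.36, Slpi -1.36, Pbsn -1.31, Pnliprp1 -1.14, Glb1l3 -1.14, Defb1 -0.97, Upk3b -0.81, Stat2 -0.78, Creb3l4 -0.70, Sdf2l1 -0.68, Upk1a -0.66, Syvn1 -0.61, Col6a3 -0.59, Nxpe3 -0.45 and Oasl1 -0.41. In 10 of these genes (Cyp4a12a, Defb42, Defb9, Emx2, Foxi1, Hoxb2, Nefh, Svs3a, Svs4 and Svs6) the lobe without a call had low wild-type signal, which left little room for a fall there. Pate14, Smgc, Slc7a12, Cckar, Chn2, Gsdma, Pnliprp1 and Nxpe3 fell to low signal in the ventral knockout, so their differences are lower bounds. Glb1l3 had low signal in both ventral genotypes (4.18 and 2.78), so the size of its difference is uncertain. Among the lists, camera at the preset correlation marked the following median differences: seminal vesicle secretory genes 1.77, fibroblast and extracellular matrix 0.84, smooth muscle 0.84, Schwann cells and nerve 0.43, apoptosis and castration-type regression 0.29, fatty acid synthesis and PPAR targets 0.24, Wnt, Hedgehog and TGF-beta signalling 0.20, oxidative phosphorylation 0.19 and immediate-early genes 0.12 on the higher side, and unfolded protein response and secretion -0.44, urothelium and urethra -0.29 and prostate secretory products -0.20 on the lower. None of these 12 list calls held with an estimated correlation, under which the adjusted p of the smooth muscle list was 0.159 and fry passed 14 lists.

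Other groupings of the same arrays were counted. The 6 arrays of a lobe make 10 splits into 3 and 3, too few for a share under 0.05: the real ventral split called 1652 genes and the highest other 0, the real lateral split 916 and the highest other 0, and for the lobes of wild-type mice 12384 and 0, so that 1 split of 10 was as large in each. Of 100 groupings drawn from the 200 that regroup genotypes within each lobe, 1 (the real one) called as many genes for the mean of both lobes (1024, highest other 313), and 1 as many for the difference between the lobes (1693, highest other 216). Among the groupings drawn, this argues against chance in how these arrays fall into groups for these counts. If the arrays of a group repeat the same animal, chance differences between animals are not excluded. A grouping that was not drawn exchanges the genotypes in 1 lobe, which turns each of these contrasts into the other. It would call 1693 genes for the mean of both lobes, more than the real grouping, and 1024 for the difference.

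The fall of 12 named genes in the ventral knockout had a median of -2.56. Lateral tissue in the wild-type ventral samples would bring all its abundant transcripts, so its share was capped in each wild-type ventral array by the fifth-lowest ratio to lateral wild-type signal among 1453 genes of at least 10 log2 units there, outside the 12 genes and the seminal vesicle list. The caps were 2.14, 1.87 and 3.02%, whereas the 12 genes needed a median of 23.0, 20.2 and 38.2% and at the least 5.34, 3.76 and 6.49% (Chn2), which argues against lateral tissue as the source of the whole fall. A share up to these caps stays open: the genes that set them, Gsdma (6.14 to 4.50) and Nxpe3 (5.17 to 4.63), fell in the ventral knockout as well. An uncharacterized locus (5.01 to 5.13), whose ratio lay under the cap in WT_VP replicates 1 and 2, did not pass. Glb1l3 (4.18 to 2.78) and Nlrp10 (4.26 to 3.05) were also lower, while Defb42 went from 4.23 to 4.10. All of these last genes had low signal in both genotypes, so the size of their change is uncertain. Without low-signal genes the caps were 4.62, 4.24 and 4.59%, and that of WT_VP replicate 2 lay above the need of Chn2 there. A smaller share of luminal epithelium as the source of these 12 falls is argued against by the luminal list, whose median was -0.033 (quartiles -0.17 and 0.086), far above that of the 12 genes. They were picked as the largest falls, so the comparison speaks to them alone. Each of the 12 genes needed its largest share in WT_VP replicate 3, where seminal vesicle genes stood apart. Tissue of a lobe not arrayed here and an effect of Med1 loss stay open.

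The fall of 12 named genes in the lateral arrays labelled knockout came with lower stromal lists. A smaller stromal share as the source of these 12 falls is argued against by the smooth muscle median of -0.40 (quartiles -0.57 and -0.28), against -3.70 for the 12 genes. They were picked as the largest falls, so the comparison speaks to them alone, and a smaller stromal share itself stays open. Seminal vesicle tissue in the wild-type lateral samples may account for part of the fall of the 12 genes, since the seminal vesicle list fell with them (median -1.95, quartiles -3.05 and -0.34), although 2 of the 12 genes belong to that list and Ceacam10, a vesicle product picked after its value was seen, was at -0.007 (mean 10.47 in wild type). Svs2 and Svs4 did not keep 1 ratio, since in KO_LP replicate 3, Svs2 read 8.71 and Svs4 8.28, against 11.89 and 8.77 in KO_LP replicate 1. An effect of genotype on the lateral epithelium predicts the same fall and stays open, as does a difference in dissection, since how many of the list's genes lateral prostate itself expresses cannot be read from these arrays.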

How the results depend on the processing

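The joint removal of WT_VP replicate 3 and KO_LP replicate 3, where seminal vesicle genes stood apart, was chosen only after seeing the data, and the other settings before. Counts are given in the order ventral, lateral, mean of both lobes, difference between lobes, and lateral against ventral. At least 1.5-fold at adjusted p under 0.05 left 634, 423, 233, 1204 and 6896, 1.5-fold at unadjusted p under 0.01 left 658, 459, 233, 1337 and 6869, adjusted p under 0.10 gave 2704, 1509, 1558, 2726 and 13336, and every probe set gave 2576, 1384, 1503, 2600 and 30301, as the thresholds and the number of features tested imply. Without the dimmest 60% of genes the counts were 1348, 568, 782, 1093 and 5943, with fewer genes tested. The arrays compared alone gave 965 ventral and 841 lateral genes, with fewer samples. The labels do not say whether same-numbered arrays share an animal. Same-numbered deviations correlated at -0.0608 to 0.116 (1 of 12 pairs over 0.1), which shows no clear pairing but cannot exclude it. If they do share an animal, the contrasts over both lobes treat lobes of the same animal as independent. With the number as a fixed replicate block the counts were 992, 775, 968, 1323 and 12583, and with a random replicate block 1647, 918, 1041, 1654 and 12363. With each array left out in turn they ranged from 941 to 1760, 499 to 1168, 778 to 1115, 1103 to 1732 and 11485 to 12746. The lowest were without WT_VP replicate 3 for the ventral count, WT_LP replicate 1 for the lobes and WT_LP replicate 3 for the rest. The joint removal gave 860, 583, 635, 973 and 11537. With an array left out Med1 ranged from -0.64 to -0.48 in the ventral lobe, where it no longer passed without KO_VP replicate 3 (-0.48, limma adjusted p = 0.0518), and from -0.27 to -0.01 in the lateral lobe, where the mean of its probe sets gave 0.045. Ventral lists past the threshold numbered 7, with fry 11, with an estimated correlation 0 and with an array left out 7 to 10. Lateral lists numbered 14, with an estimated correlation 1, with quantile normalization 11, without the dimmest 40% of genes 9 and with an array left out 11 to 15. The share of higher calls moved with median centring from 64.7% to 48.2% ventral, 32.1% to 44.4% lateral and 69.9% to 47.7% for the difference, and with quantile normalization from 18.1% to 55.3% between the lobes. Where neither fewer genes nor fewer samples is involved, the cause was not tested. For the named genes that had passed, 4101 checks under an alternative passed in the same direction, 320 no longer passed and 0 reversed, and for lists 357 and 42. These genes were picked for large changes or small p, so the checks say little about the other calls. Of all 1652 ventral calls, 896 (54.2%) still passed without WT_VP replicate 3, the lowest share with an array left out. For the 916 lateral calls the lowest was 473 (51.6%), without WT_LP replicate 3. Signal over background limits what dim genes can show.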

Other observations

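The families and genes described here were chosen after their values were seen, as were the tests of the hypotheses. Of 33 measured genes of the Hox clusters, which mark position along the body axis, 9 fell, 1 rose and 23 did not pass in the lateral arrays labelled knockout (limma). The falls included Hoxd9 (-1.99 ± 0.13, limma adjusted p = 6.97e-07), Hoxd8 (-1.70), Hoxb4 (-0.93), Hoxb6 (-0.85), Hoxb3 (-0.80) and Hoxb2 (-0.75), while Hoxb13 was at -0.068 and Hoxa10 at -0.066. Quantile normalization gave as many of each, and median centring 8 lower and 2 higher. The family was picked for these changes, so no test of it as a group is given. In the ventral lobe 1 of the 33 rose and 0 fell by limma (0 and 0 under quantile normalization, 1 and 1 under median centring). The effect on Hoxd9 differed between the lobes (2.04 ± 0.19, ventral minus lateral, limma adjusted p = 2.55e-05). Hoxd9 and Hoxd8 averaged 8.83 and 8.75 in wild-type lateral, 6.84 and 7.05 in lateral arrays labelled knockout, and 6.33 and 6.61 in wild-type ventral prostate. Seminal vesicle tissue and a difference in dissection, left open above for the lateral falls, were not tested for these genes or the families below.

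Of 17 measured genes of the circadian clock, also picked for their changes and not tested as a group, 5 fell, 1 rose and 11 did not pass in the lateral lobe (limma), and 4 fell under quantile normalization or median centring. In the ventral lobe 0 of the 17 passed under any of the 3. The output gene Dbp was at -1.27 ± 0.18 (limma adjusted p = 8.84e-04), the repressor Nr1d1 at -0.94 and Bhlhe40 at -0.77, and Cry1 rose by 0.59. Arntl was at 0.042 (limma adjusted p = 0.914). The effect on Dbp differed between the lobes (1.52 ± 0.26, ventral minus lateral, limma adjusted p = 0.00235). Hour of tissue collection was not part of the model, so a difference in it between the groups was not tested. Of 20 measured beta-defensins, 6 fell and 1 rose in the lateral lobe (5 and 1 under either scaling), with Defb13 at -1.47 and the rise in Defb2 at 1.01. Defb9 (3.39) and Defb11 (3.62) ended at low signal, so their changes of -2.25 and -2.10 are lower bounds. In the ventral lobe 2 fell and 1 rose (1 and 1 under quantile normalization), with Defb1 at -0.99.

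The 111 genes that changed in the same direction in both lobes are a pattern that differences in strain background could also give. Among the 50 nearest measured genes on each side of Med1, 0 of 100 belonged to this set, against 111 of 18045 elsewhere (Fisher's exact test, p = 1, odds ratio 0, 95% interval 0 to 6.17). Alleles of another strain carried along in this window were not detected, and the interval leaves them open. Genes beyond the window counted as elsewhere, so a longer stretch around Med1 was not tested. Elsewhere 9 pairs of these genes lay within 5 measured genes of each other, against a median of 3 in 10000 random sets (permutation p = 0.0042). In 5 of the pairs, such as Selenop and Ghr, both genes changed in the same direction as each other, and in 4 in opposite directions. The random sets were drawn from all measured genes with a position and were not matched for signal, so the excess does not single out strain alleles. Blocks of strain alleles elsewhere in the genome could give it, while shared control of neighbouring genes was not tested and stays open. An effect of Med1 loss common to both lobes stays open as well.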
